A study of Mus musculus with 6 samples.

How the data were processed

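The series measured RNA of cultured fibroblasts from fibrotic mouse lungs carrying a TGF-alpha transgene, in 6 libraries: 3 with a control siRNA (numbered 1 to 3) and 3 with an siRNA against Wt1 (numbered 4 to 6). Groups and numbers were taken from the sample titles, which call the cells resident fibroblasts and both duplexes stealth siRNAs. Total RNA was purified on silica columns and standard Illumina libraries were made, per the labels' protocols. The sequences of the siRNAs and the time between transfection and harvest are not given in the sources used here.

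The deposited table holds raw whole-number counts of reads per gene, without normalization, with 1 row for each of 24061 Entrez gene IDs and 1 column per library. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat, DESeq and the mouse genome build mm10 (GRCm38), without a role or order. The counting tool, the annotation, the strand setting and any filter are not given in the sources used here. Reads of paralogs and of antisense genes could therefore be split or shared in ways that cannot be checked, and values of close gene families are reported as uncertain. Column totals were 26.1 to 32.1 (in units of 1e6), which makes 3 counts in a library worth 0.0935 to 0.115 CPM. The 10 most abundant genes took 7.75% to 12.1% of the counts of a library.

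Gene IDs were matched to symbols, coordinates and transcript lengths with the RefSeq annotation of GRCm38.p6 (23976 IDs) and with GENCODE for 7 more. The other 78 IDs were left unnamed but kept in the tests, and held 0.435% to 1.71% of the counts of a library. Of the 24061 genes 6192 had no count in any library.

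The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter (14190 genes kept), a model with the siRNA group alone, and Benjamini-Hochberg adjustment at 0.05. TMM factors were 0.940 to 1.07, and the common biological coefficient of variation was 0.191. CPM values use the TMM factors. The standard error of a log2 fold change is the absolute log2 fold change divided by the square root of F, and is not given where a group had no reads. Log2 CPM for principal components and list tests used a prior count of 2.

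Within groups the Pearson correlation of log2 CPM, across genes, was 0.968 to 0.977, and between groups 0.949 to 0.966. Chi-square values per degree of freedom for pairs within a group, over genes with at least 10 reads in the pair, were 18.9 to 70.9, so that no pair was a repeated sequencing of 1 library. This does not tell preparations of 1 culture from separate cultures; the 6 libraries were counted as separate samples because the labels list them so.

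Before the data were examined, the test, the filter, 33 gene lists, the alternatives and the rule for named genes were fixed. The lists cover mitosis, replication, contractile genes and collagens as the main ones, other pathways, markers of cell types that the cultures could hold, and genes that track RNA quality. A list was tested where at least 5 members passed the filter, which left 32; the mitochondrially encoded genes had 0 members in the table and were not analysed here. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists), and again with an estimated correlation and with fry. Camera compares a list with the other genes, while the directional p of fry asks whether the members move, on balance, one way. Of the 32 lists 10 passed camera with the preset correlation, 5 higher and 5 lower, 0 with an estimated correlation, and 16 passed fry. Some genes are in more than 1 list. Another 3 lists, of ATF4 targets, endoplasmic reticulum chaperones and lysosomal genes, were tested apart from the 32. They were written after the named genes were seen and before their own values were looked up as lists. The lysosomal list was prompted by the rise of Rragd, which the rule for named genes did not pick, and shares 1 gene with the fixed lists.

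The named genes are Wt1, Acta2, Col1a1, Col3a1, Fn1, Mki67 and Ccnb1; the 6 largest rises and 6 largest falls among genes with adjusted p below 0.05, mean log2 CPM of at least 2, groups that did not overlap and a symbol that is not a clone or predicted-gene name; and, for each list, the members with the smallest p among those past the threshold, 3 for a main list, 2 for another list that passed camera and 1 for the rest. This gave 60 genes, of which 58 are described here. Genes named outside the rule, such as Actg2, Acta1, Wt1os, Msln, Krt19, Nkain4, Eng, Lyz2 and Rragd, were chosen after their values were seen.

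The procedure was tested on simulated counts drawn for the 14190 genes from their means, dispersions and library sizes, with 200 genes changed in each of 5 simulations. It recovered 24.6% of genes changed 1.5-fold, 69.4% of those changed 2-fold and 88.6% of those changed 4-fold, all with the right sign, and 6.69% of its calls were false. A list lowered 1.5-fold passed camera in 5 of 5 simulations, and 0 of 155 tests of unchanged lists passed; the simulated genes were independent, unlike real ones.

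The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, no filter, a filter of at least 5 CPM in at least 3 libraries, robust shrinkage, leaving out each library in turn, adjusted p thresholds of 0.01 and 0.1, glmTreat against a fold of 1.2, and, for the lists, an estimated correlation, fry and voom weights.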

Results

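RNA sequencing counts were examined for 6 libraries of mouse lung fibroblasts kept in culture, which the sample titles call resident fibroblasts. The cells came from fibrotic lungs of mice carrying a transgene for TGF-alpha, a ligand of the epidermal growth factor receptor. In 3 libraries the cells had received a control siRNA, and in the other 3 an siRNA against Wt1, the Wilms tumor transcription factor with zinc fingers. An siRNA is a short RNA duplex that directs the degradation of a matching transcript. Total counts were 30.4, 28.2 and 26.1 (in units of 1e6) in control libraries 1 to 3 and 27.5, 29.4 and 32.1 in Wt1 siRNA libraries 4 to 6. The comparison sets transcripts after Wt1 siRNA against those after control siRNA. Sequences of the duplexes are not given in the sources used here, so that effects on other transcripts with a partial match are not separated from those of lower Wt1. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

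Wt1 itself (gene ID 22431, GRCm38 chromosome 2, 105126529 to 105173614, counted over the whole gene) was measured first. It stood at 48.8, 55.7 and 51.5 counts per 1e6 counts of the library (CPM) in the control libraries and at 11.4, 8.63 and 7.92 CPM after Wt1 siRNA. The means were 52.0 ± 3.50 and 9.31 ± 1.83 CPM (SD, n = 3), a log2 fold change of -2.48 ± 0.16 (SE), or 5.59-fold lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.98e-06). All 3 libraries with Wt1 siRNA lay below all 3 controls. Wt1os, the antisense transcript annotated beside Wt1 on the same chromosome (105076538 to 105126510), had 0.699 CPM in controls and 1.40 CPM after Wt1 siRNA (adjusted p = 0.267). The annotated spans of Wt1 and Wt1os do not overlap.

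After Wt1 siRNA, all tested mitosis genes and most interferon-stimulated genes were lower, the collagen gene Col1a1 was 2.18-fold higher, and Masp1, Slc7a3 and Gdf15 were higher. Of 14190 genes tested, 1284 were higher and 1459 lower at an adjusted p below 0.05 (edgeR), which is 19.3% of the genes tested. At least 2-fold changes were found in 247 genes that were higher and 454 that were lower. An unadjusted p below 0.05 was found for 4551 genes, against 710 by chance. In 5168 genes, 36.4% of those tested, the libraries of the groups did not overlap, where chance gives 10%. Scaling by library size alone gave 855 higher and 1829 lower genes, so that the share of higher genes was 31.9% in place of 46.8%. Without Wt1 siRNA library 4 the counts were 578 higher and 785 lower, and without Wt1 siRNA library 5 there were 836 higher.

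Among called genes with a mean log2 CPM of at least 2, groups that did not overlap and a symbol other than a clone or predicted-gene name, the largest rises were those of Masp1, a serine protease of the lectin complement pathway, and Slc7a3, a cationic amino acid transporter. Masp1 went from 18.7 ± 2.77 to 111 ± 22.0 CPM (log2 fold change 2.57 ± 0.17, adjusted p = 5.98e-06, and at most 2.71 with a library left out). Slc7a3 went from 1.33 ± 0.54 to 7.69 ± 2.07 CPM (2.53 ± 0.35, adjusted p = 5.82e-04, and 2.84 without control library 2, where it passes Masp1). They were followed by Acss3, a short-chain acyl-CoA synthetase (2.38 ± 0.47, and 3.0 without control library 1, where it passes Masp1), Gdf15, a stress-induced cytokine (2.21 ± 0.22), Nell2, a secreted glycoprotein (2.13 ± 0.36), and Cth, the cystathionine gamma-lyase that makes cysteine (2.09 ± 0.22). The largest fall under the same conditions was that of Angptl7, a secreted angiopoietin-like protein, from 20.4 ± 4.10 to 1.26 ± 0.25 CPM (log2 fold change -4.00 ± 0.25, adjusted p = 5.98e-06). Il1rl1, the receptor for interleukin 33, fell by 3.31 ± 0.52 on the log2 scale (-2.69 without control library 3 and -4.19 without Wt1 siRNA library 6, where it passes Angptl7 at -4.13). Adcyap1r1, the receptor of the neuropeptide PACAP, fell by 2.96 ± 0.38 (-3.55 without Wt1 siRNA library 6). Akr1c18, a hydroxysteroid dehydrogenase (-2.87 ± 0.49, a member of a family of similar copies, so that reads could be shared), and Hp, haptoglobin (-2.67 ± 0.31), were also lower. Spp1, osteopontin, was far more abundant and varied more: 1803, 1540 and 3544 CPM in the controls against 198, 177 and 725 CPM (log2 fold change -2.65 ± 0.49, adjusted p = 0.00288). With robust shrinkage the adjusted p of Spp1 was 0.0592, and without Wt1 siRNA library 6 its log2 fold change was -3.61.

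**Figure D1:**
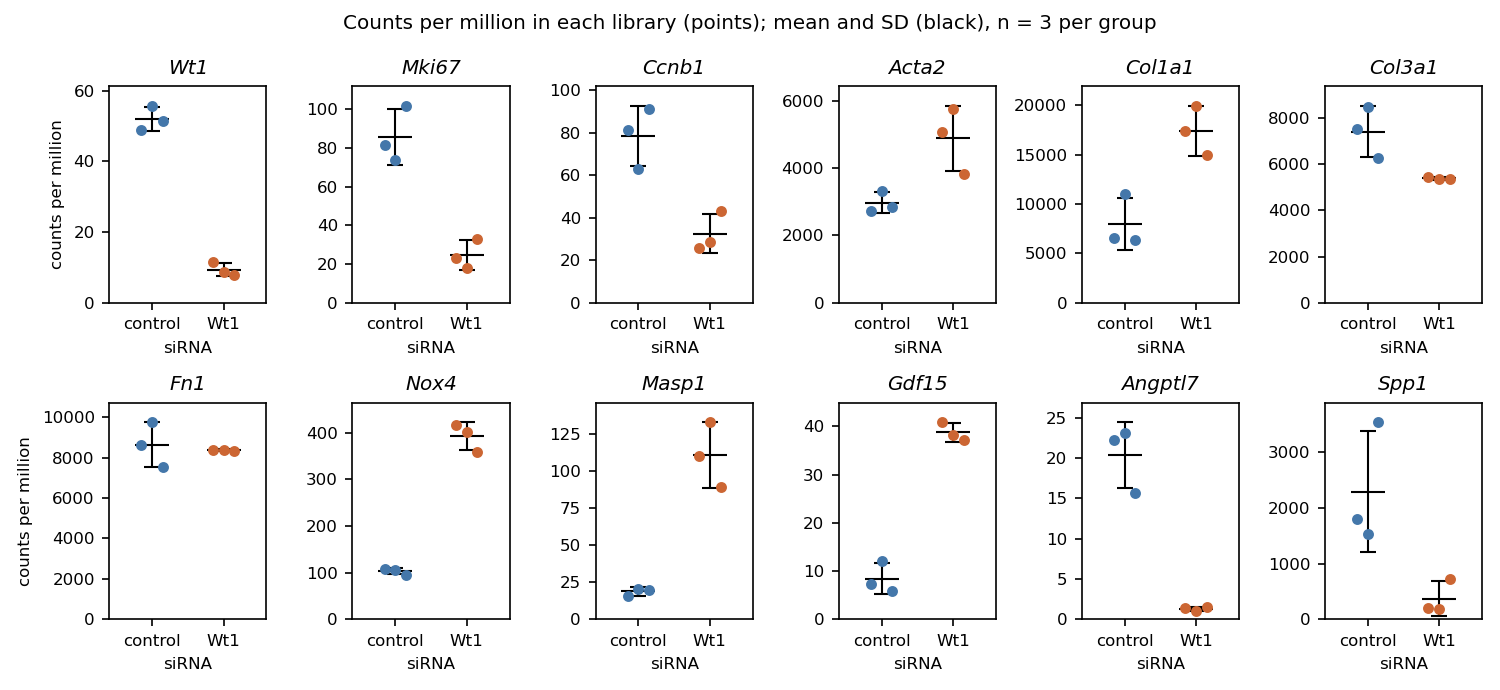
CPM of 12 genes in each library, with control siRNA on the left and Wt1 siRNA on the right of each panel; points are libraries, and the black marks are the mean and SD of 3. Wt1 lies between 48.8 and 55.7 CPM in the controls and between 7.92 and 11.4 CPM after Wt1 siRNA, and the groups overlap only for Fn1 among the genes shown.

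Genes of cell division fell together. All 32 tested genes of the mitosis and G2/M list were lower (edgeR, DESeq2 and limma-voom), with a median log2 fold change of -1.18, the smallest fall being 0.88. The count was also 32 when adjusted over the list alone. Mki67, the proliferation marker Ki-67, fell from 85.7 ± 14.5 to 24.6 ± 7.81 CPM (3.48-fold lower, adjusted p = 1.72e-04). Ccnb1, cyclin B1, fell from 78.5 ± 14.2 to 32.5 ± 9.33 CPM (-1.27 ± 0.19, adjusted p = 9.61e-04). The kinetochore genes Cenpf (-1.45 ± 0.16) and Cenpe (-1.45 ± 0.16) fell likewise. The list was lower by camera with its preset correlation (adjusted p = 1.01e-18), but the adjusted p = 0.514 with an estimated correlation.

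Of 32 genes of DNA replication and the G1/S transition, 13 were lower, 0 higher and 19 did not pass (edgeR). The higher count was also 0 at an unadjusted p below 0.05, with DESeq2 and with limma-voom. Adjusted over the list alone, 19 were lower. The list median was -0.69, and 30 of the 32 log2 fold changes were negative. Lig1, the replicative DNA ligase, fell by 1.38 ± 0.19, Rrm1, the large subunit of ribonucleotide reductase, by 0.87 ± 0.13, and Mcm3, a subunit of the replicative helicase, by 0.80 ± 0.14 on the log2 scale (adjusted p = 4.52e-04, 8.47e-04 and 0.00192). The camera test gave an adjusted p = 1.07e-05, and the adjusted p = 0.514 with an estimated correlation. The number of lower members was 8 without control library 1, 6 without control library 3, 6 without Wt1 siRNA library 4 and 7 without Wt1 siRNA library 5.

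**Figure D2:**
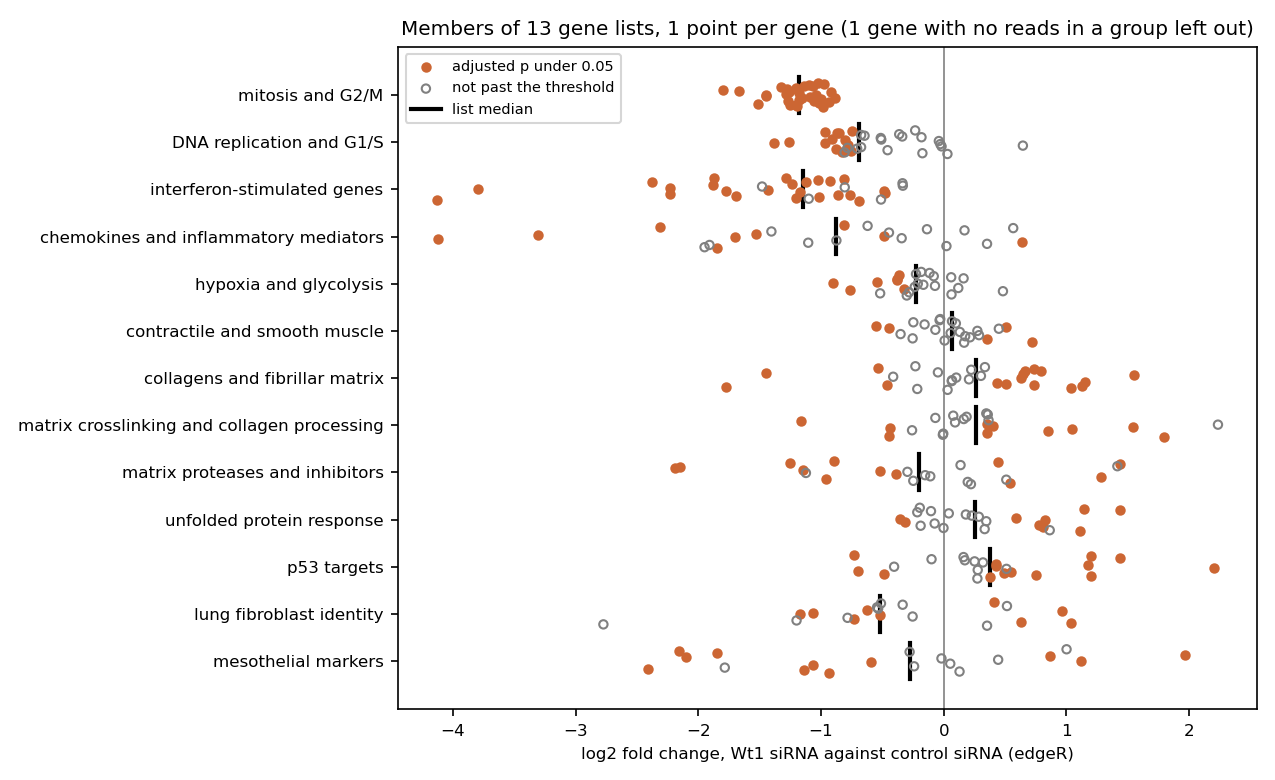
Log2 fold changes (horizontal axis, Wt1 siRNA against control siRNA, edgeR) of the tested members of 13 gene lists, with filled points at adjusted p below 0.05, open points for the rest and a bar at each list's median. All 32 mitosis and G2/M genes lie at or below -0.88, while the collagen and fibrillar matrix genes spread to both sides, with 12 higher and 4 lower.

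The contractile genes did not move as a group. Acta2, smooth muscle actin and a marker of myofibroblasts, rose from 2960 ± 314 to 4881 ± 966 CPM (log2 fold change 0.72 ± 0.14, adjusted p = 0.00399). Its sequence is close to that of other actins, whose reads could be shared with it; Actg2 had a log2 fold change of 0.01 ± 0.18 and Acta1 of 0.17 ± 0.16, and neither passed. Of 23 contractile and smooth muscle genes 3 were higher and 2 lower (4 and 4 adjusted over the list alone), with a median of 0.07 that turned to -0.02 with library size scaling. The lower count was 4 with DESeq2 and 5 with library size scaling. Pdlim7, an actin-associated protein, rose by 0.51 ± 0.12 and Smtn, smoothelin, fell by 0.55 ± 0.12 on the log2 scale. The list did not pass camera (adjusted p = 0.657). Without Wt1 siRNA library 4, 1 member was higher and 1 lower, and the adjusted p of Pdlim7 was 0.0624.

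The collagen genes went in both directions. Col1a1, a chain of type I collagen, rose from 7982 ± 2651 to 17421 ± 2514 CPM (log2 fold change 1.13 ± 0.19, adjusted p = 0.00172), with control library 2 at 11040 CPM and the other controls at 6554 and 6352 CPM. Col3a1, the chain of type III collagen, fell from 7430 ± 1121 to 5391 ± 69.2 CPM (-0.46 ± 0.11, adjusted p = 0.0135). Fn1, fibronectin, had 8642 ± 1101 and 8365 ± 38.1 CPM, a log2 fold change of -0.05 ± 0.10 that did not pass (adjusted p = 0.810). Of 28 collagen and fibrillar matrix genes 12 were higher, 4 lower and 12 did not pass (14 and 4 adjusted over the list alone), with a median of 0.26. Fbln5, an elastic fibre protein, rose by 1.55 ± 0.12, Col5a3, a type V collagen chain, by 1.15 ± 0.13, and Postn, the matricellular protein periostin, by 0.79 ± 0.10. The list was higher by camera (adjusted p = 0.0207), with adjusted p = 0.514 with an estimated correlation and 0.0614 without control library 3. Without Wt1 siRNA library 4 the adjusted p of Col3a1 was 0.0708.

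Of 22 genes of matrix crosslinking and collagen processing 7 were higher and 3 lower (9 and 3 adjusted over the list alone), with a median of 0.27. Loxl4, a lysyl oxidase, rose from 17.8 ± 0.43 to 51.9 ± 6.70 CPM (1.55 ± 0.13), and Adamts14, a procollagen protease, from 9.11 ± 1.54 to 31.7 ± 0.98 CPM (3.48-fold, adjusted p = 3.52e-05). The list passed camera (adjusted p = 0.0286), with adjusted p = 0.651 with an estimated correlation. It was at 0.0789, 0.112 and 0.0668 without control library 1, control library 3 and Wt1 siRNA library 5, and at 0.0591 with the stricter filter. The number of higher members was 11 without control library 2 and 4 without control library 1, control library 3, Wt1 siRNA library 4 or Wt1 siRNA library 5, and 1 member was lower without control library 2, Wt1 siRNA library 4 or Wt1 siRNA library 6. With library size scaling 4 were higher.

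Matrix proteases and their inhibitors, 22 genes, held 4 that were higher and 8 that were lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.346). Mmp8, a collagenase, fell from 415 ± 22.5 to 93.7 ± 16.8 CPM (-2.15 ± 0.14, adjusted p = 5.98e-06). The lower count was 5 without control library 1 or Wt1 siRNA library 5. Among 22 basement membrane genes 6 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.133, and 0.0404 without control library 2). Lama2, the laminin alpha-2 chain, rose by 1.17 ± 0.11. Without Wt1 siRNA library 4 the higher count was 3, and the lower count was 1 without control library 1, control library 2, Wt1 siRNA library 4 or Wt1 siRNA library 6.

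Genes of growth factor signalling were split. Of 23 TGF-beta response genes 6 were higher and 5 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.922), and 3 were lower without control library 3 or Wt1 siRNA library 4. The camera direction of that list was up, while its median of -0.02 and mean of -0.04 were negative. Nox4, an NADPH oxidase induced by TGF-beta, had the smallest p of all genes and rose from 103 ± 7.14 to 393 ± 30.2 CPM (1.93 ± 0.11, adjusted p = 5.98e-06). Of 21 PDGF, FGF and VEGF growth factors and receptors 5 were higher and 9 lower (5 and 10 adjusted over the list alone; camera adjusted p = 0.310). Pdgfra, the PDGF receptor alpha of fibroblasts, fell from 1181 ± 70.9 to 523 ± 96.4 CPM (-1.17 ± 0.13, adjusted p = 1.48e-04). The lower count of that list was 3 without control library 1 and 4 without Wt1 siRNA library 4, and the higher count was 2 without control library 3 or Wt1 siRNA library 6 and 3 without Wt1 siRNA library 4 or with library size scaling.

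Of 23 Wnt pathway genes 7 were higher and 8 lower (7 and 9 adjusted over the list alone; camera adjusted p = 0.383). Sfrp1, a secreted Wnt inhibitor, fell from 1329 ± 92.1 to 367 ± 53.3 CPM (-1.86 ± 0.12, adjusted p = 5.98e-06). Of 16 genes of the insulin-like growth factor axis 3 were higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.907), and 0 were higher without Wt1 siRNA library 4. Igfbp4, an IGF binding protein, fell by 1.57 ± 0.13. None of 18 EGF receptor ligands and receptors passed in either direction in edgeR or limma-voom (0 adjusted over the list alone; camera adjusted p = 0.922), while at an unadjusted p below 0.05 1 was higher and 1 lower. With DESeq2 or library size scaling, or without control library 2 or Wt1 siRNA library 6, 1 of these was lower. Among 35 genes reported as WT1 targets in other tissues, 8 were higher and 6 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.907). Their camera direction was up, while the median of -0.03 and mean of -0.01 were negative. Snai1, a transcription factor of epithelial to mesenchymal transition, fell by 1.17 ± 0.14. The higher count was 5 without control library 1, control library 3 or Wt1 siRNA library 5.

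Targets of p53 and genes of the unfolded protein response were more often higher than lower. Of 23 p53 targets 11 were higher and 3 lower (13 and 4 adjusted over the list alone), with a median of 0.38. Sesn2, sestrin 2, rose from 54.8 ± 4.51 to 148 ± 10.8 CPM (1.44 ± 0.11, adjusted p = 1.78e-05) and Trp53inp1 from 99.0 ± 2.76 to 227 ± 8.16 CPM (2.30-fold, adjusted p = 2.24e-05). The list passed camera (adjusted p = 0.00120), with adjusted p = 0.514 with an estimated correlation, and 7 members were higher without Wt1 siRNA library 4. Of 22 genes of the unfolded protein response 7 were higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.26. Besides Sesn2, which is in both lists, Asns, asparagine synthetase, rose from 125 ± 3.48 to 271 ± 19.2 CPM (1.11 ± 0.10, adjusted p = 4.88e-05). The unfolded protein response list passed camera (adjusted p = 0.0247), with adjusted p = 0.514 with an estimated correlation and 0.0613 without control library 3. Its lower count was 1 without control library 1, control library 2 or Wt1 siRNA library 5, and 0 without control library 3, Wt1 siRNA library 4 or Wt1 siRNA library 6. Of 24 apoptosis regulators 7 were higher and 4 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.412). Cflar, an inhibitor of caspase 8 activation, fell by 0.80 ± 0.12. The higher count of that list was 4 without control library 1 or Wt1 siRNA library 5 and 3 without Wt1 siRNA library 4, and the lower count was 1 without control library 1, control library 3, Wt1 siRNA library 4 or Wt1 siRNA library 5.

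Interferon-stimulated genes fell together. Of 30 tested, 24 were lower, 0 higher and 6 did not pass (edgeR), with 28 lower when adjusted over the list alone. No member was higher at an unadjusted p below 0.05, with DESeq2 or with limma-voom (0 in each), and all 30 log2 fold changes were negative (median -1.14). Eif2ak2, the protein kinase activated by double-stranded RNA, fell from 128 ± 8.55 to 55.4 ± 2.44 CPM (2.30-fold lower, adjusted p = 3.52e-05). Zbp1, a sensor of nucleic acids in the Z form, fell from 36.4 ± 9.70 to 9.94 ± 1.78 CPM (-1.87 ± 0.20, adjusted p = 1.44e-04). The list was lower by camera (adjusted p = 2.64e-13), with adjusted p = 0.514 with an estimated correlation. Members of the Ifit, Oas and Gbp families are similar in sequence, so that their single values are uncertain. Of 12 macrophage and monocyte markers 1 was lower, Cd14, a coreceptor for bacterial lipopolysaccharide (18.7 ± 2.69 to 8.41 ± 2.34 CPM, -1.15 ± 0.22), and the list median was -0.39 (camera adjusted p = 0.412; 1 lower adjusted over the list alone).

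Of 23 chemokines and inflammatory mediators 9 were lower and 1 higher (10 and 1 adjusted over the list alone), with a median of -0.87. Cxcl14, a chemokine of fibroblasts and epithelium, fell from 877 ± 79.4 to 270 ± 91.6 CPM (-1.70 ± 0.19, adjusted p = 1.64e-04). Il33, an alarmin cytokine, fell from 38.7 ± 2.85 to 13.3 ± 3.38 CPM (-1.53 ± 0.17, adjusted p = 1.72e-04), and Il1rl1, its receptor, fell as given above. The list was lower by camera (adjusted p = 3.98e-04), with adjusted p = 0.514 with an estimated correlation. Cxcl5, a neutrophil chemokine, had no reads after Wt1 siRNA against 42 counts over the controls, and with it at its bound (3 counts over the group) the list median was also -0.87. Without control library 3, 2 members were higher. Among 5 lymphocyte and granulocyte markers 1 was lower, the calcium-binding protein S100a8 of neutrophils (5.19 ± 2.55 to 0.488 ± 0.514 CPM, -3.36 ± 0.69; camera adjusted p = 0.550; 1 adjusted over the list alone), and this count was 0 with the stricter filter. Without Wt1 siRNA library 6 the log2 fold change of S100a8 was -4.66.

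**Figure D3:**
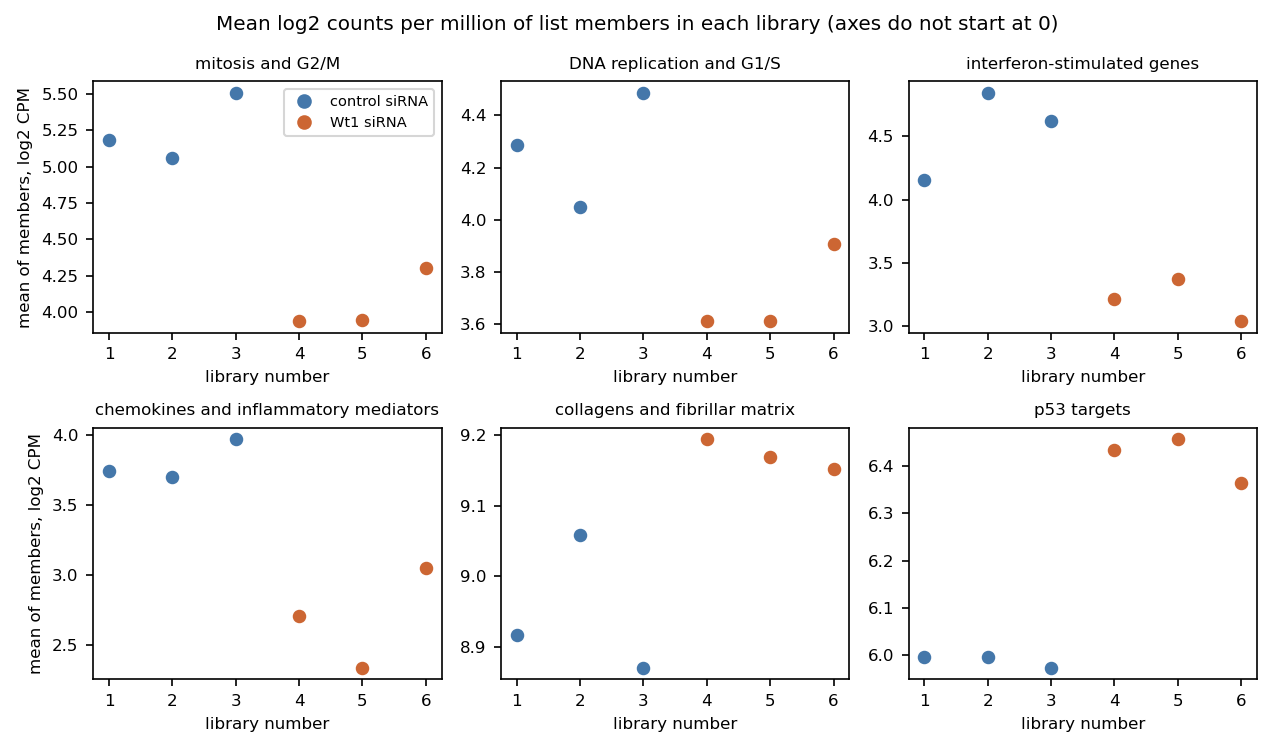
Mean log2 CPM over the members of 6 gene lists (vertical axes, which do not start at 0) in each library, numbered 1 to 6 on the horizontal axis, with control siRNA in blue and Wt1 siRNA in orange. The interferon-stimulated list lies at 4.15, 4.84 and 4.63 in the controls and at 3.21, 3.37 and 3.04 after Wt1 siRNA.

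Of 23 genes of hypoxia and glycolysis 7 were lower and 0 higher (7 and 0 adjusted over the list alone; 10 and 0 at an unadjusted p below 0.05; 7 and 0 in DESeq2 and limma-voom), with a median of -0.23. Ndrg1, a gene induced by low oxygen, fell from 257 ± 22.0 to 137 ± 10.6 CPM (-0.91 ± 0.11, adjusted p = 2.51e-04), and Egln3, a prolyl hydroxylase that senses oxygen, from 89.1 ± 8.61 to 52.3 ± 6.82 CPM (-0.77 ± 0.13, adjusted p = 0.00160). The list was lower by camera (adjusted p = 0.0180), with adjusted p = 0.570 with an estimated correlation, and was at 0.0590 without control library 2 and 0.0618 without Wt1 siRNA library 6. Its lower count was 2, 4 and 3 without Wt1 siRNA libraries 4, 5 and 6.

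Markers of fibroblasts went in both directions, more of them down. Of 19 lung fibroblast identity genes 4 were higher and 5 lower (4 and 10 adjusted over the list alone, camera adjusted p = 0.163). The median log2 fold change was -0.52, with 13 negative, 6 positive and the lowest at -2.77. The lower count was 9 with DESeq2 and 8 with library size scaling. Plin2, a lipid droplet coat protein, rose from 138 ± 9.19 to 269 ± 17.2 CPM (0.96 ± 0.10, adjusted p = 1.44e-04), while Pdgfra, also in this list, fell as given above. Of 19 mesothelial markers, a cell type of the lung surface that expresses Wt1, 8 were lower and 3 higher (8 and 3 adjusted over the list alone; median -0.28; camera adjusted p = 0.0807, and 0.0344 without Wt1 siRNA library 5). Lrrn4 fell from 70.9 ± 8.49 to 16.5 ± 2.73 CPM (-2.10 ± 0.15, adjusted p = 1.27e-05). The 3 markers that rose, named after their values were seen, were Msln, mesothelin (21.3 to 38.8 CPM), the keratin Krt19 (17.9 to 39.0 CPM) and Nkain4 (1.58 to 6.22 CPM).

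Markers of other cell types gave few calls. Of 13 epithelial markers 2 were lower and 0 higher (2 and 0 adjusted over the list alone; 3 and 0 at an unadjusted p below 0.05; 3 and 0 in DESeq2; camera adjusted p = 0.155). Aqp5, a water channel of alveolar cells, went from 3.22 ± 0.21 to 0.449 ± 0.224 CPM (-2.84 ± 0.49), and 1 epithelial marker was lower without control library 2 or Wt1 siRNA library 4 or with the stricter filter. Of 17 endothelial markers 1 was higher and 1 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.905). The lower one was Kdr, a VEGF receptor, at 17.2 ± 3.88 and 9.36 ± 2.31 CPM (-0.88 ± 0.23), whose call was lost without control library 1, control library 3 or Wt1 siRNA library 4 (adjusted p = 0.0587, 0.0878 and 0.0904). The higher one, Eng, which was named after its value was seen, had 81.0 and 112 CPM, and the higher count was 0 without control library 1, control library 3, Wt1 siRNA library 4 or Wt1 siRNA library 5 and with upper-quartile or library size scaling. Of 15 pericyte and vascular smooth muscle markers 2 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.884, direction up with a median and mean of -0.06). Gucy1b1, a subunit of the nitric oxide receptor, rose by 0.99 ± 0.12 on the log2 scale. The lower count of that list was 0 without Wt1 siRNA library 4, and 2 with DESeq2 or no filter.

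Lists that track RNA quality gave few calls. Of 41 cytosolic ribosomal protein genes 0 were called in edgeR (0 adjusted over the list alone), with 8 higher and 0 lower at an unadjusted p below 0.05, 4 higher in DESeq2 and 2 in limma-voom. Their median was 0.15, and the list was higher by camera (adjusted p = 0.0291), with adjusted p = 0.651 with an estimated correlation, 0.102, 0.0719 and 0.30 without control library 2, control library 3 and Wt1 siRNA library 6, and 0.127 with library size scaling. The higher count was 2 without control library 1 and 1 without control library 3 or Wt1 siRNA library 5, and 1 member was lower without Wt1 siRNA library 6. Of 16 replication-dependent histone genes, a family of similar copies whose transcripts lack a poly(A) tail, 1 was lower, H2ac6 (-0.83 ± 0.26, adjusted p = 0.0464; 0 adjusted over the list alone; camera adjusted p = 0.137, and 0.0244 with no filter). That count was 0 without control library 1, control library 2, control library 3, Wt1 siRNA library 4 or Wt1 siRNA library 5, where the adjusted p of H2ac6 was 0.0910, 0.0549, 0.139, 0.0977 and 0.153, and without Wt1 siRNA library 6 it was 0.0690. Of 15 reference genes for quantitative PCR 1 was lower and 0 were higher (1 and 0 adjusted over the list alone; 4 higher at an unadjusted p below 0.05, 1 in DESeq2; camera adjusted p = 0.295). Without control library 3, 1 was higher.

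The list tests have a limit that holds for every list above, as 0 of 32 passed camera with an estimated correlation. The 6 libraries were also divided into groups of 3 in the other 9 ways. In these, camera with the preset correlation passed between 1 and 9 lists, against 10 in the real comparison. Each of these splits sets unequal numbers of control and Wt1 siRNA libraries against each other, so that part of a real difference stays in it. They therefore do not show how many lists camera would pass where no list had changed. The numbers of list members called by edgeR do not rest on camera.

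**Figure D4:**
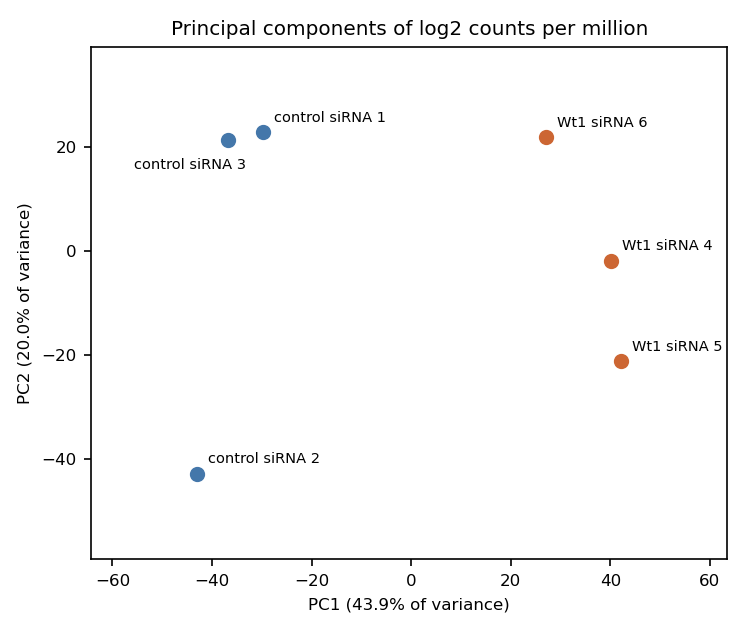
First and second principal components of log2 CPM (arbitrary units), 1 point per library, control siRNA in blue and Wt1 siRNA in orange. The first component holds 43.9% of the variance and separates the groups, and the second, with 20.0%, sets control library 2 at -42.8 apart from control libraries 1 and 3 at 22.7 and 21.3.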

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

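All alternatives were chosen before the data were examined. No paired analysis was run, because the labels give no pairing and the library numbers 1 to 3 and 4 to 6 are not shared between the groups. On the second principal component libraries 1 to 3 lay at 22.7, -42.8 and 21.3, and libraries 4 to 6 at -1.87, -21.2 and 21.8. A pairing of the libraries in order of number is not known and was not tested. Wt1 was lower under every alternative run, with log2 fold changes from -2.65 (without Wt1 siRNA library 4) to -2.38 (without Wt1 siRNA library 6). No named gene that was called and no list past the camera threshold changed direction in the alternatives run. Fn1, which was not called, had a log2 fold change of 0.05 without control library 2, and with library size alone the medians of the contractile and EGF receptor lists, neither past the threshold, turned to -0.02 and -0.05. Of the 2743 genes called by edgeR, DESeq2 also called 2732 and limma-voom 2679 in the same direction. Of the 59 named genes other than Wt1, 59 kept their call status with DESeq2, RLE, upper-quartile and library size scaling and with no filter, 58 with limma-voom (H2ac6 lost) and with robust shrinkage (Spp1 lost), and 55 to 58 with each library left out; the stricter filter tested 56 of them, and all 56 kept their status. Runs with a library left out have fewer samples, but their counts also depended on which library was left out. There were 1253 higher and 1406 lower genes without control library 2, and 578 and 785 without Wt1 siRNA library 4. The cause of these and of the other changes was not tested, except where the alternative itself is stricter or tests fewer genes.

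Library size alone gave 855 higher genes, a threshold of 0.01 gave 562 higher and 766 lower, and glmTreat gave 591 higher and 858 lower. The stricter filter, which kept 10745 genes, left 159 genes higher at least 2-fold. With a library left out, 578 to 1253 genes were higher and 785 to 1406 lower.

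With an estimated correlation the adjusted p was 0.514 for mitosis, replication, collagens, p53 targets, interferon-stimulated genes, chemokines and the unfolded protein response, 0.570 for hypoxia and 0.651 for crosslinking and ribosomal proteins. With fry crosslinking was at 0.0530 and ribosomal proteins at 0.253, while matrix proteases and Wnt (0.0431 each), PDGF/FGF/VEGF factors, heat shock and mesothelial markers (0.0250 each), apoptosis (0.0421), fibroblast identity (0.0318) and macrophage markers (0.0477) passed. Ribosomal proteins were at 0.127 with library size alone and, like crosslinking, at 0.0591 with the stricter filter, and histones passed at 0.0244 with no filter. With a library left out, the adjusted p of camera ranged from 0.0404 to 0.303 for basement membrane, 0.00277 to 0.0614 for collagens, 0.00199 to 0.30 for ribosomal proteins, 0.00349 to 0.0618 for hypoxia, 0.00247 to 0.112 for crosslinking, 0.0344 to 0.241 for mesothelial markers and 0.00691 to 0.0613 for the unfolded protein response.

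With DESeq2, 4 contractile, 1 EGF receptor, 9 fibroblast identity, 2 pericyte and 2 histone genes were lower, and 2 heat shock, 4 ribosomal and 1 reference gene higher. With limma-voom, 2 heat shock and 2 ribosomal genes were higher and 0 histones lower. With upper-quartile factors 0 endothelial markers were higher. With library size alone, 5 contractile, 1 EGF receptor, 8 fibroblast identity and 2 histone genes were lower, and 4 crosslinking, 3 PDGF/FGF/VEGF, 0 cholesterol and 0 endothelial genes higher. With no filter, 1 unfolded protein response, 2 pericyte and 2 histone genes were lower and 3 ribosomal genes higher. With the stricter filter, 2 heat shock and 1 ribosomal gene were higher, and 0 lymphocyte and 1 epithelial marker lower. With robust shrinkage, 2 heat shock and 1 ribosomal gene were higher.

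With a library left out, the higher members numbered 3 to 7 for apoptosis, 3 to 6 for basement membrane, 1 to 2 for chemokines and for heat shock, 0 to 2 for cholesterol and for ribosomal proteins, 1 to 4 for contractile genes, 0 to 1 for endothelial markers and reference genes, 5 to 8 for WT1 targets, 0 to 3 for the insulin-like growth factor axis, 4 to 11 for crosslinking, 7 to 11 for p53 targets and 2 to 4 for PDGF/FGF/VEGF factors. The lower members numbered 1 to 4 for apoptosis and for adhesion, 1 to 2 for basement membrane, cholesterol, epithelial markers and crosslinking, 1 to 3 for contractile genes, 0 to 1 for ribosomal proteins, EGF receptor genes, endothelial markers, pericyte markers, histones and the unfolded protein response, 6 to 17 for replication, 2 to 7 for hypoxia, 5 to 8 for matrix proteases, 3 to 9 for PDGF/FGF/VEGF factors and 3 to 4 for TGF-beta response.

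Depth limits genes of low expression, as 3 counts equal 0.0935 to 0.115 CPM. In simulated data, over genes of any expression that were tested, 24.6% of 1.5-fold changes were recovered. Those data held 200 changed genes, against 2743 called here, and the adjustment is stricter where fewer genes change. The share therefore does not carry over directly, but a gene without a call may still have changed by such a fold.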

Other observations

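The tests of macrophage, monocyte, lymphocyte and granulocyte markers, of variation from dish to dish, of mesothelial markers and of the difference between mitosis and replication genes were chosen only after the result was seen. Of 20 cholesterol synthesis genes 3 were higher and 2 lower (3 and 2 adjusted over the list alone; median -0.03; camera adjusted p = 0.907). The lower count was 1 without control library 1, control library 3, Wt1 siRNA library 4 or Wt1 siRNA library 5. The higher count was 0 without control library 2, Wt1 siRNA library 4 or Wt1 siRNA library 5, and with library size scaling.

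Of 15 heat shock genes 1 was higher and 2 lower (2 and 2 adjusted over the list alone; median -0.07; camera adjusted p = 0.678), with 2 higher without control library 1 and with DESeq2, limma-voom, the stricter filter or robust shrinkage. Hspd1, the mitochondrial chaperonin, fell from 244 ± 23.3 to 114 ± 4.02 CPM (-1.10 ± 0.11, adjusted p = 7.11e-05). Of 23 integrins and cadherins 3 were higher and 4 lower (3 and 4 adjusted over the list alone; median -0.09; camera adjusted p = 0.749). Itga6, a laminin-binding integrin chain, rose from 48.3 ± 10.7 to 97.3 ± 3.13 CPM (1.01 ± 0.15, adjusted p = 6.67e-04). The lower count of that list was 2 without control library 1 or control library 3 and 1 without Wt1 siRNA library 4 or Wt1 siRNA library 5.

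All 32 mitosis genes were called lower under each of 3 other scalings (RLE, upper-quartile and library size alone). These scalings differ little: the median log2 fold change of all genes was 0.003 with TMM and -0.08 with library size alone. The choice among them therefore does not account for log2 fold changes of -0.88 or lower, and a shift that all of them miss was not tested. After a trend on GC content and transcript length was removed, over 13463 genes, the list median was -1.16, against -1.18 before. Growth that varies from dish to dish whatever the siRNA is argued against, if the libraries are separate dishes, by the list means, whose groups differ by 1.19 (log2 CPM) while the larger range within a group is 0.449. A growth state that all dishes of a group share cannot be told apart from an effect of the siRNA, because the design puts it on the same libraries, and the 100% of member and library pairs that were lower after Wt1 siRNA do not separate them. No biological explanation of the fall was tested.

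The fall of the interferon-stimulated genes did not rest on control library 2, the one with the highest list mean, as 20 of 30 members were lower without it. A loss of macrophages and monocytes as large as the fall of the interferon list is argued against by their markers. The median of the markers was -0.39 against -1.14 for the interferon list. Their mean lay 1.04 above that of the interferon list (standard error of the difference of means 0.23, with genes taken as independent). Still, 8 of the 12 markers had a negative log2 fold change, and the list was lower by fry (adjusted p = 0.0477), so that a smaller loss is not excluded. Of the abundant markers Lyz2 had 19.7 CPM in controls and 21.7 CPM after Wt1 siRNA, while Cd14 fell from 18.7 to 8.41 CPM. The 19 lymphocyte and granulocyte markers together held 14.3 CPM in controls and 8.63 CPM after Wt1 siRNA. The interferon-stimulated genes lost 633 CPM, 44.3 times the level of these markers in controls. This argues against the lost reads being mainly those of such cells themselves. The mean of the tested markers lay 0.48 above that of the interferon list (standard error of the difference of means 0.68), which does not separate the lists. A loss of lymphocytes or granulocytes is therefore not excluded. Effects of any of these cells on the genes of the fibroblasts were not tested. Whether the duplexes differ in how they trigger interferon cannot be told apart from an effect of Wt1: the titles call both stealth siRNAs, a modified type meant to limit interferon responses, but no untransfected library is among the samples to set against the control mean of 4.54 (log2 CPM).

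Cth, Asns, Sesn2 and Gdf15 rose, and lists of other genes, written after these were seen but before their own values were, tested whether a wider program moved with them. Of 34 ATF4 targets for amino acid synthesis, transport and tRNA charging, 21 were higher and 1 lower, Cebpb (-0.56 ± 0.13), with a median of 0.54 (camera p = 1.69e-10; p = 0.0941 with an estimated correlation; p = 0.00206 with fry). Slc7a5 rose by 1.39 ± 0.15, Psat1 by 1.11 ± 0.14 and Wars by 1.25 ± 0.14, named after their values were seen, and Atf4 itself had 379 and 477 CPM (adjusted p = 0.0927). A general rise of endoplasmic reticulum chaperones is not borne out by a second list (limma camera, adjusted p = 0.389 over the 3 second lists), although a p that misses the threshold does not show that chaperones did not differ. The values are those that an activated amino acid response could give, but camera with an estimated correlation (p = 0.0941) did not pass. In another split of the libraries camera p for the ATF4 list reached 5.17e-08. That split keeps part of the real difference, so that it does not decide how far the camera test can be trusted.

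Rragd, a GTPase of the lysosomal amino acid sensor, rose from 11.6 to 41.2 CPM (1.83 ± 0.16, adjusted p = 2.96e-05), while a list of 34 lysosomal genes had a limma camera p of 0.366. Among the mesothelial markers 3 rose past the threshold, which a loss of mesothelial cells alone would not give. These rises do not decide whether such a loss lowered the 8 markers that fell. The mean log2 fold change was -1.19 for mitosis and -0.58 for replication genes, a difference of -0.61 with p = 1e-05, the smallest that 100000 permutations of the list labels over genes can give; genes of a list are correlated, which that test ignores.

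The 6 libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real comparison gave 1284 higher and 1459 lower genes, and 247 and 454 at 2-fold or more. Only 1 of 10 splits, the real one, reached each of these counts. The highest of the other 9 was 0 in each (edgeR), with 105 to 1148 genes at an unadjusted p below 0.05. The other tools were not run on these splits. In the other 9 the real difference adds to the spread within the groups, which lowers the number of calls. The 0 therefore does not show how many calls libraries without a difference would give. Part of the real difference also stays between the groups of these splits, which can lower camera p for lists that changed. For gene lists past the camera threshold the real value was 10 and the highest other 9. That split set control libraries 1 and 3 and Wt1 siRNA library 6 against the rest, and also had the 1148 genes, so that the libraries hold a structure besides the groups. In the other splits camera gave a smaller p than the real comparison for 5 of the 10 lists past the threshold: replication (1.27e-08 against 1.00e-06), collagens (0.00289 against 0.00453), crosslinking (1.28e-04 against 0.00804), hypoxia (4.67e-04 against 0.00338) and ribosomal proteins (4.36e-07 against 0.00909). For the other 5 the lowest p of the other splits was larger: mitosis (3.03e-11 against 3.14e-20), interferon-stimulated genes (3.36e-13 against 1.65e-14), p53 targets (0.0143 against 1.88e-04), chemokines (6.98e-05 against 4.97e-05) and the unfolded protein response (0.0152 against 0.00618).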
